A study of Parasteatoda tepidariorum with 3 samples.

How the data were processed

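Single cells and single nuclei of late stage 5 spider embryos were profiled in 3 libraries: cells 1 (10 embryos), cells 2 (20 embryos) and nuclei 2 (20 embryos). Per the labels' protocols, embryos were freed of chorion and vitelline membrane by bleach and by hand. Cells were strained. Nuclei were released by homogenization in a detergent buffer, washed and strained. Both were kept in a preservative at 4 °C until capture on the BD Rhapsody microwell platform, and the nuclei were lysed longer, with Proteinase K. The submitters' processing notes name STAR 2.5.2b and Seurat 4.0.3, without saying what each did. The genome build and gene annotation are not given in the sources used here.

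Each library came with 4 deposited tables. The first holds deposited counts of molecules per gene and barcode before filtering (552, 5361 and 5145 barcodes). The next, here called the first filtered table, holds the same counts for 505, 3621 and 4720 barcodes. Every entry was checked to equal the unfiltered one, and the 1114, 1004 and 183 genes left out of it had 0 counts in the unfiltered table. Of the barcodes taken out in cells 1, 46 of 47 held more UMIs than any barcode kept. In cells 2, 1694 held fewer and 46 more than any kept, and in nuclei 2, 362 held fewer and 63 more. The third table leaves out further genes: 445 genes with 48.7% of the molecules in cells 1, and 85 genes with 3.29% and 2.06% in cells 2 and nuclei 2. The reason is not given in the sources used here. The last holds deposited natural log values, which equal ln(1 + count / total × 10000) of the third table with differences under 1e-09, as checked from the values.

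Because the third table takes a different part out of cells 1, the deposited counts of the first filtered table were used for all sums and tests. The third table was used for clustering, for matching clusters, for marker lists and for calling doublets. Gene columns carry NCBI gene numbers. There were 19188, 18376 and 20360 of these in the 3 libraries, and 14232 were in all 3, with 94.8%, 96.7% and 94.0% of the molecules. Only these genes entered the sums and tests, which left 8120116, 50820120 and 24437840 molecules. Clustering, the CPM of clusters and the total UMIs of a cell used every column of the table they came from. Names came from the RefSeq gene table of assembly CAS_Ptep_4.0, which holds 79.6%, 85.3% and 83.5% of the numbers. It was used for names only, since the build of the counts is not known. In it 39 genes carry a descriptive synonym, so most genes stay unnamed. Of 23 gene lists fixed before the data were examined, 9 had at least 1 named gene and 6 had at least 3 tested. Of the small lists, Notch had Delta alone, the cumulus had decapentaplegic and patched, and BMP had decapentaplegic and short gastrulation. The lists for Sox factors, ribosomal proteins, mitochondrial genes, respiration, translation, proteasome, splicing, chromatin, histones, cell cycle, adhesion, stress, germ cells and yolk were not analysed here.

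Counts were summed per library over the barcodes kept, because cells are not replicates. Cells and nuclei were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05). The TMM factors were 0.775, 0.605 and 2.13, and the common dispersion was 0.435, a coefficient of variation of 0.659. Standard errors are the size of the log2 fold divided by the square root of F. The fixed lists, and all positional genes together, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Each list median was also placed among 10000 random lists of equal size drawn from bins of mean expression.

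For cells with and without a reference gene, the first 4 of a fixed order with at least 30 positive cells in every library were taken: hedgehog, fork head, decapentaplegic and Delta. Negative cells were drawn within deciles of total UMI, up to 5 per positive cell. For decapentaplegic and Delta in every library, and for hedgehog in cells 2 and nuclei 2, the draw took every negative cell, so it matched no depth there. The 6 sums were tested in edgeR with a term for the library (2 residual degrees of freedom), without the reference gene itself. A difference of effect between nuclei and cells was tested as an interaction in the same model, a test added after the data were seen. With 1 library of nuclei it has 1 residual degree of freedom, from the 2 cell libraries, and assumes that the nuclei vary like them. EdgeR pools this spread with that of other genes.

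Clusters were found within each library with scanpy 1.11.5: counts scaled to 10000 per cell, log transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, seed 0. Clusters were matched by the correlation of mean profiles. Cell type names needed 3 detected markers from a list fixed before the data were examined. Since such markers were detected in more than 1 cluster of a library, no cluster was given a name. Scrublet called 5, 2 and 3 barcodes doublets in cells 1, cells 2 and nuclei 2 (0.990%, 0.0552% and 0.0636%), which is too few to rely on, and they were kept. Marker lists of 20 genes were scored by mean pairwise Spearman correlation against 1000 lists matched on expression. Where shares of cells with a UMI are compared across libraries, cells were also thinned to 2500 UMIs, which left out 4 nuclei and 0 cells.

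Genes were named by a rule fixed before the data were examined. It took every identified member of the positional and signalling lists that was detected in all 3 libraries. For cells against nuclei it took the 10 genes with the largest fold in each direction among those that passed with 1 direction in both cell libraries and a mean of at least 50 CPM, which named 0 genes, since 0 passed. For each reference gene it took the 5 with the largest fold in each direction among those that passed with 1 direction in every library, of which at most 2 unnamed gene numbers per direction are printed. The genes leading a cluster define it and are not results.

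The steps were tested on simulated data. With counts drawn at a dispersion of 0.4, close to that of cells against nuclei, edgeR recovered 0, 0 and 1 of 200 genes changed 2-, 4- and 8-fold among 12222, 12193 and 12204 genes, and DESeq2 recovered 4, 17 and 61 with 28, 63 and 62 false calls. At a dispersion of 0.01 edgeR recovered 98.5%, 100% and 100%. In the hedgehog comparison at that dispersion it recovered 100% at each fold size, with 11, 6 and 6 false calls among 10539, 10559 and 10554 genes. Simulated log2 odds ratios of 0, 1 and 3 came back as 0.10 ± 0.09, 0.96 ± 0.24 and 3.16 ± 0.14. In simulated cells a list of 20 genes sharing a program lay at the 100th percentile, and 0 of 40 unrelated lists reached the 95th.

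The alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter on low counts, every barcode, thinned counts, each library left out, an estimated correlation, at least 2 UMIs for detection, other negative cells and draw seeds, no library term, other clustering settings and no depth strata. Intervals are exact Clopper-Pearson at 95% and, like all values of single libraries, cover counting error only. P-values cover at most the spread between these 3 libraries, which may be technical. EdgeR pooled that spread over genes, so the p-value and SE of a gene need not reflect its own spread between libraries.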

Results

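Whole embryos of the common house spider Parasteatoda tepidariorum were profiled at late stage 5, the late germ-disc stage, when the embryo is an epithelial disc with its future anterior at the rim and its future posterior at the centre. The embryos were wild type and had been kept at 25 °C. Dissociated cells came from 10 embryos (cells 1) and from 20 embryos (cells 2), and isolated nuclei came from 20 embryos (nuclei 2), so that there were 2 libraries of cells and 1 of nuclei. Polyadenylated RNA was captured from single cells or nuclei in microwells on the BD Rhapsody platform, and each molecule was counted once by its molecular identifier (UMI). The barcodes kept after the deposited filtering numbered 505, 3621 and 4720 in cells 1, cells 2 and nuclei 2, with 8561140, 52571531 and 26003086 molecules in total. The median cell held 16402 UMIs over 3325 genes in cells 1 and 14207 UMIs over 3101 genes in cells 2. The median nucleus held 5404.5 UMIs over 2565.5 genes. The labels do not say whether the libraries came from separate clutches, so the spread between them, and every p-value built on it, may be technical.

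The molecules of the nuclei were spread over more genes than those of the cells. The 100 most abundant genes of each library took 41.4% of the molecules in both cell libraries and 14.7% in nuclei 2. The 2 cell libraries resembled each other more than either resembled the nuclei. Across 14229 genes detected in at least 1 library, Pearson's r of log2(CPM + 1) was 0.938 between the cell libraries, with a Spearman's rho of 0.919. Between cells 1 and nuclei 2 r was 0.798 and rho 0.811, and between cells 2 and nuclei 2 r was 0.848 and rho 0.874. These are correlations across genes within single libraries, and genes are not independent replicates. Over the 5169 genes with at least 10 CPM in every library, r was 0.904 between the cell libraries, 0.429 between cells 1 and nuclei 2 and 0.510 between cells 2 and nuclei 2.

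Cells and nuclei were compared to ask which transcripts each preparation holds in larger amounts. Many patterning genes took a larger part of the molecules in nuclei. The transcripts of hedgehog (LOC107451809), a secreted signal of the anterior rim, made up 62.2 and 73.2 CPM in cells 1 and cells 2 and 760 CPM in nuclei 2. For short gastrulation, a secreted antagonist of BMP signalling, the values were 32.3, 25.6 and 512 CPM. For labial, an anterior Hox gene, they were 8.62, 8.36 and 145 CPM, and for smoothened, the membrane protein that transduces the hedgehog signal, 17.2, 10.6 and 189 CPM. Of 26 named patterning and signalling genes that were tested, 22 were more abundant, in CPM, in nuclei 2 than in both cell libraries. The 3 genes that were more abundant in both cell libraries were twist (LOC107440133), a mesodermal transcription factor, at 22.5, 26.2 and 8.18 CPM, hairy, at 176, 182 and 162 CPM, and armadillo, which encodes beta-catenin, at 416, 348 and 323 CPM.

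These levels have to be read against the shift of all genes, because the median gene had a log2 ratio of CPM of −1.14 for cells 1 over nuclei 2 and −1.48 for cells 2 over nuclei 2. After TMM scaling, which takes out most of this shift, edgeR's quasi-likelihood test called 0 of 12749 genes at a Benjamini-Hochberg adjusted p under 0.05, and 3211 genes had an unadjusted p under 0.05. DESeq2 called 1767 genes on the same sums, 1390 higher in cells and 377 higher in nuclei. Scaled by library size alone, edgeR called 484 genes higher in cells and 2540 higher in nuclei, with a median log2 fold of −1.53. With no filter on low counts it called 2032 genes. The nuclei form 1 library, so the spread came from the 2 cell libraries with 1 residual degree of freedom, and the nuclei were assumed to vary like them. EdgeR pooled this spread with that of other genes (4.56 prior degrees of freedom). At the simulated dispersion of 0.4, edgeR recovered 0, 0 and 1 of 200 genes changed 2-, 4- and 8-fold. Its lack of calls here therefore does not show that cells and nuclei were alike. DESeq2's false calls outnumbered the changed genes it recovered. Only 200 genes were changed in those counts, so this false share cannot be carried over to its calls here. Whether they were held to the threshold is not known.

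Among the named genes, 5 passed when adjusted over the list alone (adjusted p = 0.0425 for each, edgeR), and 0 of them passed over all genes. Relative to the typical gene, short gastrulation was lower in cells by a log2 fold of −2.52 (SE 0.47, adjusted p over all genes 0.0568), labial by −2.44 (SE 0.56), smoothened by −2.16 (SE 0.54) and odd-paired, a zinc-finger factor of segment patterning, by −1.92 (SE 0.47). For twist the fold was 3.24 (SE 0.75), higher in cells. Without TMM scaling, cells 2 against nuclei 2, the pair with the same library number, differed by log2 values of −4.30 for short gastrulation, −4.03 for labial, −4.10 for smoothened, −3.69 for odd-paired and 1.62 for twist. The fitted fold of hedgehog was −1.82 (SE 0.51, adjusted p over the list 0.0542) and that of decapentaplegic, a BMP ligand, −1.88 (SE 0.61, adjusted p over the list 0.0619). Armadillo (1.88, SE 0.54, adjusted p over the list 0.0542) and hairy (1.79, SE 0.55, 0.0575) came as close with a higher fitted value in cells, and Wnt7-1 (−4.06, SE 1.23, 0.0575) with a lower one. In DESeq2 short gastrulation, labial, Wnt7-1 and twist passed over all genes, Wnt7-1 with only 3 and 10 molecules in cells 1 and cells 2. At a simulated dispersion of 0.4, DESeq2's false calls (28, 63 and 62) outnumbered the changed genes it recovered (4, 17 and 61). With only 200 genes changed in those counts, it is not known whether DESeq2's calls here were held to the threshold. In edgeR, too, whether a named gene passed over all genes depended on the filter on low counts.

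By list, no list passed camera's competitive test. Of the 18 positional genes tested, 10 had a lower and 8 a higher fitted value in cells, and 1 of the 8, Antennapedia, had 0 molecules in cells 2 and nuclei 2. The 4 tested genes of the anterior rim (hedgehog, orthodenticle, labial and six3-1) had a median log2 fold of −1.84 in cells over nuclei, with an adjusted p of 0.418, and lay at the 0.33rd percentile of 10000 lists of equal size and expression. The 4 genes of the hedgehog pathway had a median of −1.24 (adjusted p = 0.500) at the 0.4th percentile. The caudal centre, with Delta, caudal and Wnt8, had a median of −0.89 (adjusted p = 0.573) at the 15.5th percentile. The 7 Wnt pathway genes had the same median at the 11.6th percentile, and 5 trunk genes had −0.87 at the 5.49th percentile, each with an adjusted p of 0.573. The 4 endoderm and mesoderm genes went both ways, from GATA-C at −2.39 to twist at 3.24, with a median of 0.39 (adjusted p = 0.573) at the 53.4th percentile. All 18 positional genes together had a median of −0.88, an adjusted p of 0.500 and the 0.19th percentile. With an estimated correlation between genes the adjusted p was 0.735 for 6 of these lists and 0.742 for the trunk genes.

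**Figure D1:**
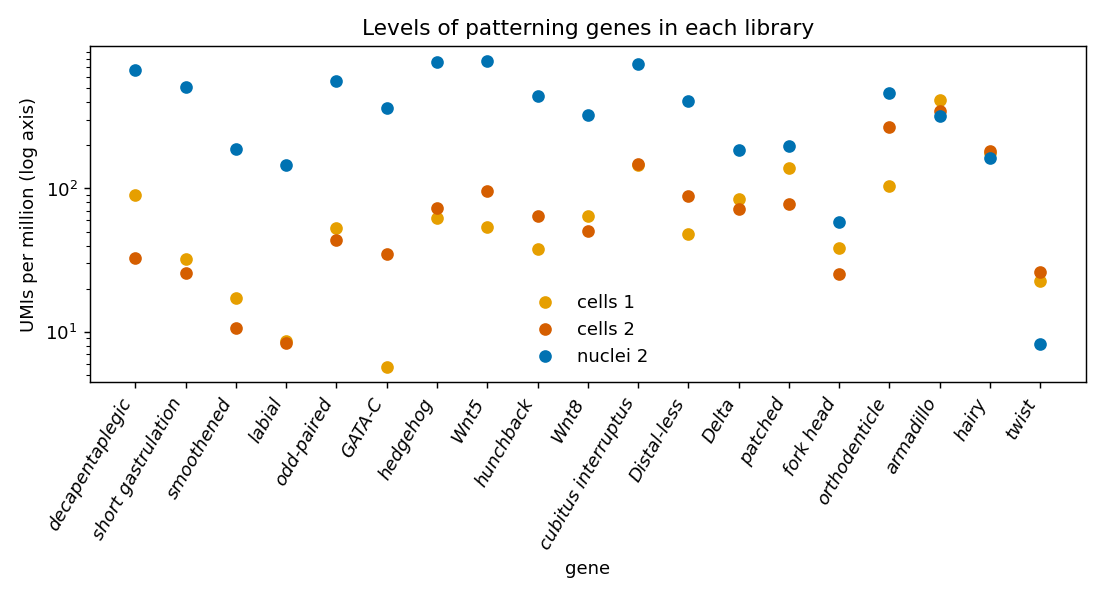
Level of each named gene with at least 5 CPM in every library, as CPM on a log axis, in cells 1, cells 2 and nuclei 2 (1 point per library). Most genes lie higher in nuclei 2, hairy and armadillo lie close together in all 3 libraries, and twist lies lower in nuclei 2 (8.18 CPM) than in the cells (22.5 and 26.2).

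Clustering within each library gave 8 clusters in cells 1, 13 in cells 2 and 11 in nuclei 2, numbered from the largest. Each library had 1 cluster with hedgehog and orthodenticle, the head-patterning homeobox gene, among its 10 leading genes, with labial also detected. That cluster held 59 of 505 cells (11.7%, exact 95% interval 9.01 to 14.8) in cells 1, 466 of 3621 (12.9%, 11.8 to 14.0) in cells 2 and 625 of 4720 nuclei (13.2%, 12.3 to 14.2). The mean of the 3 libraries was 12.6% ± 0.81 (SD, n = 3), and the intervals cover counting error only. Hedgehog had a UMI in 90.1% of the cells of this cluster in cells 2 (median 13974 UMIs) and in 0.840% of the cluster with its lowest share (median 15662 UMIs). In nuclei 2 the shares were 94.9% (median 5606 UMIs) and 8.25% (median 5255 UMIs). Over whole libraries a hedgehog UMI was found in 22.0% of the cells of cells 2 and 29.1% of the nuclei, and in 11.0% and 23.5% after thinning to 2500 UMIs.

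All clusters stay numbered, because markers of 1 class were detected in several clusters: in cells 1, labial stood at 13.7 CPM in the cluster highest in hedgehog and at 25.2 CPM in cluster 1. In each library 1 cluster had twist among its 2 leading genes, with hunchback and fork head (LOC107455300), an endoderm transcription factor, also at high levels. It held 8.91% of cells 1 (45 cells), 9.06% of cells 2 (328 cells) and 6.99% of nuclei 2 (330 nuclei), a mean of 8.32% ± 1.15 (SD, n = 3). In cells 2 the cluster highest in twist held 5.47% at a clustering resolution of 0.5 and 5.63% at 1.5. At the resolution used, twist within this cluster stood at 195, 252 and 102 CPM in the 3 libraries. A separate cluster with fork head but little twist held 47 cells in cells 1 and 170 cells in cells 2, but such cells were not limited to it. In nuclei 2 the clusters with such nuclei included cluster 8, with 176 nuclei and 442 CPM of fork head, cluster 10, with 117 nuclei and 182 CPM, and cluster 11, with 24 nuclei and 382 CPM. Across the alternatives of the clustering, the cluster of nuclei 2 highest in fork head held 24 to 182 nuclei. A cluster led by GATA-C, a GATA transcription factor, held 4.25% of cells 2 (399 CPM of GATA-C) and 6.67% of nuclei 2. With the first filtered tables clustered, an alternative chosen after seeing the data, the cluster of cells 2 highest in GATA-C held 12.8%, at 80.1 CPM. In cells 1 the highest GATA-C lay in a cluster of 38 cells that was also the highest for Delta, and across the alternatives the cluster highest in GATA-C held 3.40% to 29.7% of cells 1. In cells 2 and nuclei 2, further clusters had short gastrulation and Distal-less, labial and odd-paired, or Delta among their 10 leading genes, and 1 led by unnamed genes had the highest Wnt5 and hairy. The mean share of the cluster highest in hedgehog changed with the resolution of the clustering, to 13.8% at 0.5 and 7.92% at 1.5. At 1.5 it was 12.1%, 7.76% and 3.92% in cells 1, cells 2 and nuclei 2, and with the first filtered tables clustered it was 7.51% in cells 2.

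Clusters found in 1 library could be matched to those of the others by their mean profiles. Of the 8 clusters of cells 1, 7 were mutual best matches with a cluster of cells 2, with a median correlation over all 8 best matches of 0.847 (0.790 to 0.924) across 748 variable genes. Between cells 2 and nuclei 2 there were 8 mutual matches. The clusters with the highest hedgehog, twist, GATA-C, Wnt5, odd-paired and short gastrulation were among these, with correlations of 0.823, 0.815, 0.777, 0.849, 0.852 and 0.827. The clusters highest in Delta were not matched in both directions: cluster 9 of cells 2 had its best match in cluster 3 of nuclei 2, whose own best match was cluster 4 of cells 2. Nor was the cluster of nuclei 2 highest in fork head, with a best match in cells 2 at 0.774.

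**Figure D2:**
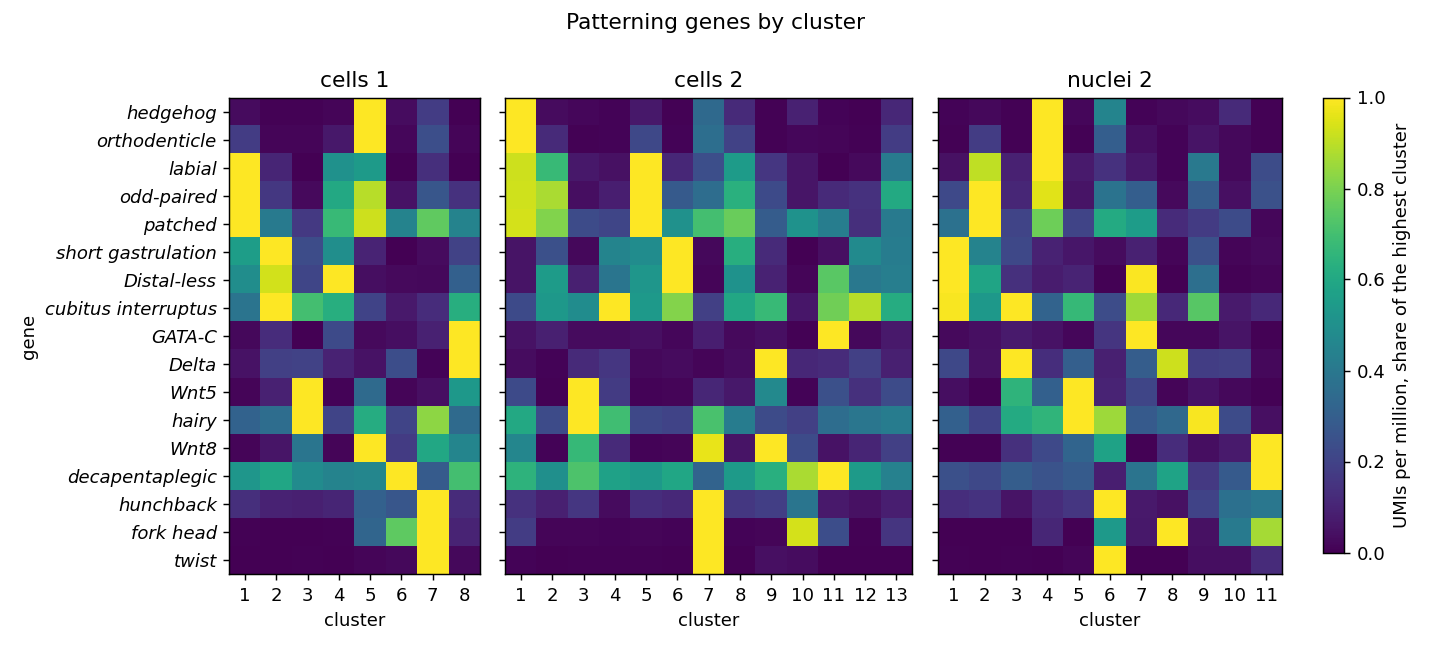
CPM of patterning genes (rows) in each cluster (columns) of cells 1, cells 2 and nuclei 2, as a share of the highest cluster of that library. In every library hedgehog and orthodenticle share their highest cluster (59 cells, 466 cells and 625 nuclei), and the cluster highest in twist (45 cells, 328 cells and 330 nuclei) is also the highest in hunchback.

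Marker genes chosen in 1 library varied together in libraries that took no part in choosing them. Lists of the 20 leading genes of each cluster of nuclei 2 were read in the cell libraries as the mean pairwise Spearman correlation of their members over cells. Of these 11 lists, 10 lay at or above the 95th percentile of 1000 matched random lists in cells 1 and 10 in cells 2. The exception in both was cluster 9, 135 nuclei with a median of 3527 UMIs, whose list lay at the 74.3rd percentile in cells 1 and the 16.8th in cells 2. Of 13 lists made in cells 2, 12 reached the 95th percentile in cells 1 and 13 did so in nuclei 2. The list of cluster 8, 173 cells, lay at the 61.5th percentile in cells 1.

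To ask which genes are used in the same part of the disc as a known positional gene, cells with at least 1 UMI of a reference gene were set against cells with 0 UMIs, summed per library. There were 93, 797 and 1375 cells or nuclei with hedgehog in cells 1, cells 2 and nuclei 2. In cells 2 and nuclei 2 every negative cell entered, and the positive ones were deeper, with medians of 14733 against 14087.5 UMIs and 5632 against 5328. The hedgehog-positive cells were higher in the other genes of the anterior rim: orthodenticle by a log2 fold of 3.47 (SE 0.05, adjusted p = 2.32e-22) and labial by 1.42 (SE 0.08, adjusted p = 5.09e-11). Wnt8 (1.44), fork head (1.16), odd-paired (0.95), hunchback (0.76), patched, the hedgehog receptor (0.63), smoothened (0.62) and hairy (0.39) were higher as well, and so was Wnt7-2 (2.19, SE 0.36). The cells without hedgehog had more Distal-less (−1.48, SE 0.10), Delta, the Notch ligand (−1.15, SE 0.11), short gastrulation (−1.08, SE 0.09), cubitus interruptus, the transcription factor of the hedgehog pathway (−0.99, SE 0.07), GATA-C (−0.53) and Wnt5 (−0.28). All of these had the same direction in each of the 3 libraries. By list, 2 of 2 tested genes of the anterior rim were higher, as were 3 of 4 trunk genes with 1 lower, and of 3 hedgehog pathway genes 2 were higher and 1 lower.

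In all, edgeR called 146 genes higher and 293 lower in hedgehog-positive cells, of 9995 tested, and 18 of 22 named genes passed both over all genes and adjusted over the list alone. The unnamed gene LOC107448560 was among the 5 genes with the largest rise (4.56, SE 0.25). DESeq2 called 229 genes, and 0 were called without a term for the library. Twist (0.51, SE 0.13) passed, but its fold was 0.37 and missed the threshold without nuclei 2, and it was −0.06 after thinning. Armadillo (−0.15, SE 0.04) missed the threshold without cells 2 (−0.18) and without nuclei 2 (−0.13).

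Cells with fork head numbered 113, 588 and 619 in the 3 libraries. Twist was the named gene with the largest difference, higher by 4.22 (SE 0.20, adjusted p = 6.35e-96, edgeR). It was followed by hunchback (2.06, SE 0.16), Wnt8 (1.61, SE 0.16), hedgehog (1.44, SE 0.16) and orthodenticle (0.73, SE 0.15). These SEs and p-values rest on spread pooled over genes. The log2 ratios of twist were 5.58, 4.09 and 3.47 in cells 1, cells 2 and nuclei 2, wider apart than its SE. Lower values were found for short gastrulation, by −3.36 (SE 0.20), Distal-less by −3.11 (SE 0.19), cubitus interruptus by −1.86 (SE 0.16), labial and Wnt5 by −1.23 each, and odd-paired by −0.85 (SE 0.16). Of the 3 tested endoderm and mesoderm genes twist was higher, while GATA-C (0.23, SE 0.18) and MEF-2 (0.73, SE 0.34) did not pass over all genes. The log2 ratio of Delta was −1.08 in cells 1, −1.03 in cells 2 and 0.26 in nuclei 2, and the interaction passed (adjusted p = 1.73e-07, edgeR). With 1 library of nuclei, the spread of Delta itself came from the 2 cell libraries alone, with 1 residual degree of freedom. EdgeR pooled it with the spread of other genes, so this p does not measure how Delta varied between libraries. Over the 3 libraries Delta had a fold of −0.71 (SE 0.16), which turned to 0.06 after thinning and missed the threshold without cells 1 (−0.55) and without cells 2 (−0.47).

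The test called 1298 genes higher and 898 lower, of 9760, with fork head. Of 21 named genes 14 passed over all genes and 15 adjusted over the list alone. The unnamed genes LOC107447507 (−4.12, SE 0.58) and LOC107447504 (−3.63, SE 0.20) were among the 5 genes with the largest fall, and both were also lower with hedgehog (−2.62 and −2.38). The balance of directions depended on the scaling: with RLE factors 1295 genes were higher and 2821 lower, in DESeq2 1172 and 2302, and in thinned cells 756 and 1035. Without cells 1 the count was 1265 and without cells 2 it was 1454. Orthodenticle (0.59), odd-paired (−0.92) and armadillo (−0.57 in all libraries, −0.60 without cells 1) lost their calls without cells 1, armadillo also without cells 2 (−0.61). Wnt16-like (1.57, SE 0.58) lost its call without cells 1 (1.80) and without nuclei 2 (1.16). The count was 0 without a term for the library.

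Decapentaplegic (LOC107442925) had a UMI in 317, 1200 and 3509 cells or nuclei of cells 1, cells 2 and nuclei 2. Its positive cells had more GATA-C (0.68, SE 0.06, adjusted p = 6.77e-04) and Delta (0.55, SE 0.09, adjusted p = 0.0136), and less twist (−1.39, SE 0.22), hunchback (−0.83, SE 0.09), Wnt8 (−0.59, SE 0.09) and fork head (−0.46, SE 0.08). Among 10276 genes 92 were higher and 22 lower, and 6 of 21 named genes passed over all genes, 10 adjusted over the list alone. None of the 3 anterior rim genes or the 4 hedgehog pathway genes passed over all genes by edgeR. The count rests largely on the nuclei: without nuclei 2 it fell to 5. Delta (0.36), Wnt8 (−0.37) and fork head (−0.38) then missed the threshold with smaller folds. GATA-C (0.66) missed it with nearly the same fold. Without cells 1 the count was 273, and without cells 2 fork head (−0.41) missed the threshold. Positive cells were deeper than negative ones (medians of 18088 against 14150.5 UMIs in cells 1, 14933.5 against 13832 in cells 2 and 5613 against 4801 in nuclei 2), since every negative cell entered. DESeq2 called 23 genes, edgeR 279 in thinned cells and 356 with no filter on low counts, and 0 without a term for the library.

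Delta (LOC107456525) had a UMI in 180, 1145 and 1389 cells or nuclei. Its positive cells had more Wnt5 (0.92, SE 0.08, adjusted p = 2.12e-10), decapentaplegic (0.45, SE 0.07), cubitus interruptus (0.41, SE 0.07), GATA-C (0.35, SE 0.09) and Wnt8 (0.33, SE 0.08). They had less twist (−1.95, SE 0.13, adjusted p = 5.42e-13), odd-paired (−0.95, SE 0.08) and patched and hunchback (−0.72 each). All 3 tested genes of the anterior rim were lower by edgeR: labial (−0.90, SE 0.11), orthodenticle (−0.72, SE 0.06) and hedgehog (−0.52, SE 0.07). Fork head (−0.54), short gastrulation (−0.52) and Distal-less (−0.39) were lower over the 3 libraries together. For Distal-less and short gastrulation cells 1 went the other way (0.51 and 0.11), and for fork head nuclei 2 did (0.12). Of 10314 genes 227 were higher and 154 lower, and 15 of 21 named genes passed over all genes, 17 adjusted over the list alone. The unnamed gene LOC107440074 was among the 5 genes with the largest rise (3.85, SE 0.11), and was lower with fork head (−3.41).

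The number of genes called with Delta was 231 without cells 2 and 173 in DESeq2, and 0 without a term for the library. Without cells 2 the calls of Wnt8 (0.15), Distal-less (−0.23), fork head (−0.27), GATA-C (0.37) and short gastrulation (−0.50) were lost, and without nuclei 2 those of labial (−0.51) and short gastrulation (−0.31). All Delta-negative cells entered, with medians of 15951, 14063.5 and 5323 UMIs against 17980, 14485 and 5631 in positive cells.

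**Figure D3:**
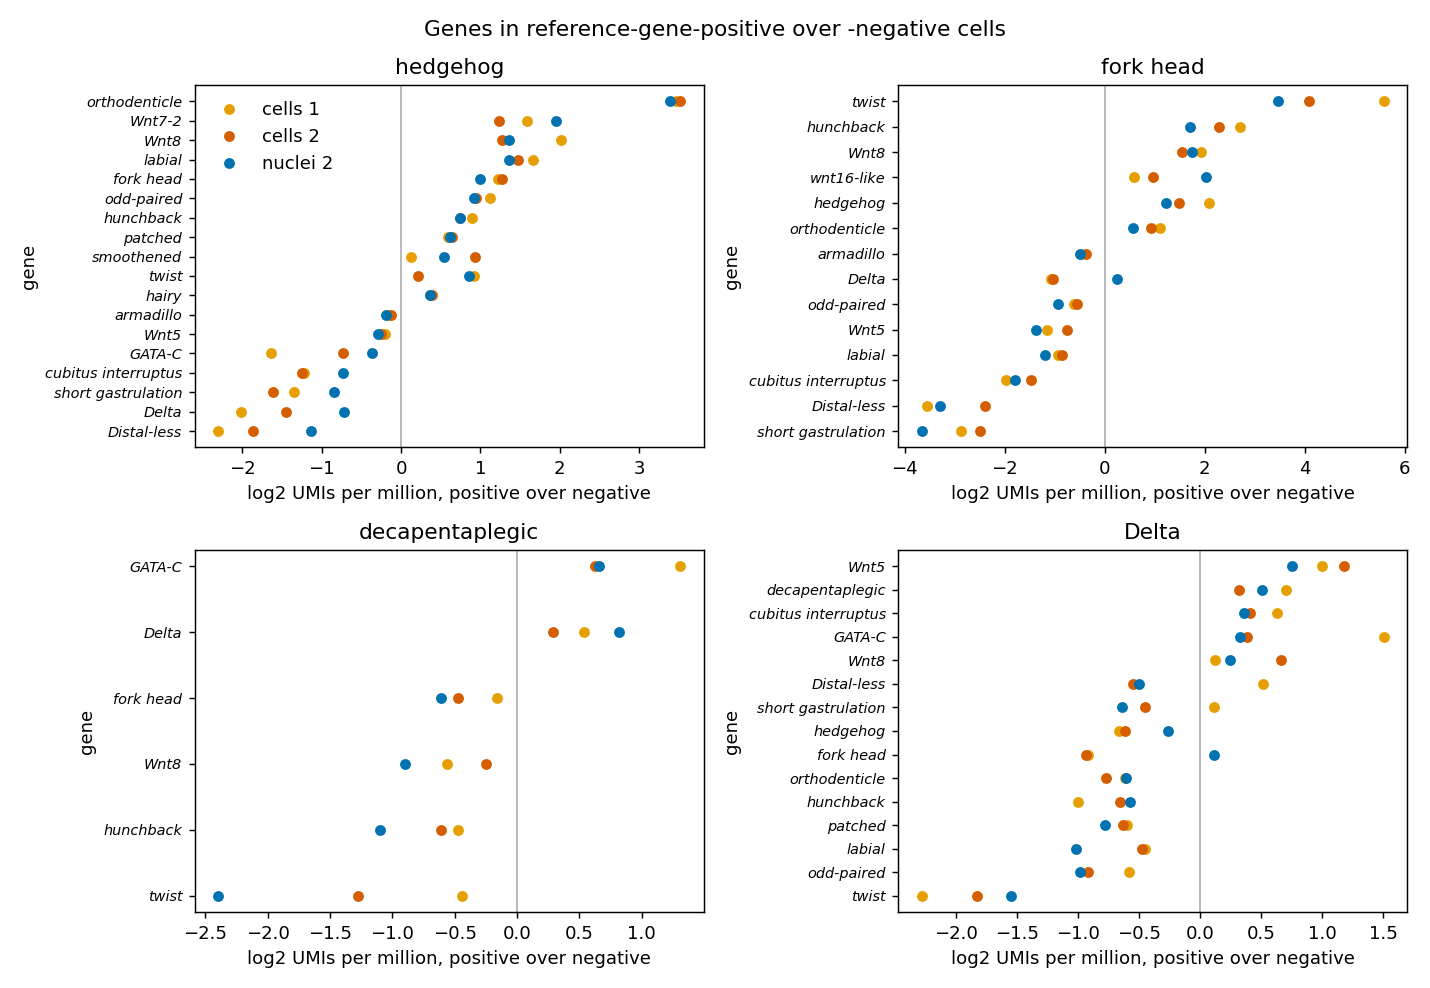
Log2 ratio of CPM in cells with at least 1 UMI of the reference gene over cells with 0 UMIs, for each named gene that passed, in cells 1, cells 2 and nuclei 2 (1 point per library, 1 panel per reference gene). Orthodenticle with hedgehog and twist with fork head stand apart to the right, and Delta with fork head lies at −1.08 and −1.03 in the cells and at 0.26 in the nuclei.

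Detection of gene pairs in the same cell was compared among 13 patterning genes, as a Mantel-Haenszel log2 odds ratio within deciles of total UMI in each library. Of 78 pairs, 40 were above 0 in all 3 libraries, 28 were below 0 in all 3 and 10 were mixed. Values are the mean ± SD of the libraries (n = 3), with no test. The largest values joined the mesodermal gene twist with fork head (4.42 ± 0.83) and with hunchback (4.23 ± 0.26), and hedgehog with orthodenticle (4.13 ± 0.64). Labial and odd-paired were at 2.57 ± 0.46, orthodenticle and labial at 2.28 ± 0.15, orthodenticle and odd-paired at 2.02 ± 0.14 and orthodenticle and patched at 1.62 ± 0.01. Hedgehog and fork head had a value of 1.82 ± 0.30, and Wnt8 and fork head one of 1.60 ± 0.07. Delta and Wnt8 had a value of 0.82 ± 0.29.

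The lowest values separated Distal-less from twist (−3.47 ± 0.78), from fork head (−3.40 ± 0.80) and from hedgehog (−2.26 ± 0.92). Delta and twist had a value of −2.03 ± 1.10, with −3.30 in cells 1, −1.32 in cells 2 and −1.48 in nuclei 2. With odd-paired the value was −1.22 ± 0.08 for Wnt8 and −1.20 ± 0.07 for Delta. Delta and fork head were at −1.32 and −1.05 in cells 1 and cells 2 and at −0.28 in nuclei 2, below 0 in each. Hunchback and Distal-less were mixed, from −1.60 in cells 1 to 0.18 in nuclei 2. With at least 2 UMIs needed for detection, 54 pairs had 1 sign in every library and 6 had no value.

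**Figure D4:**
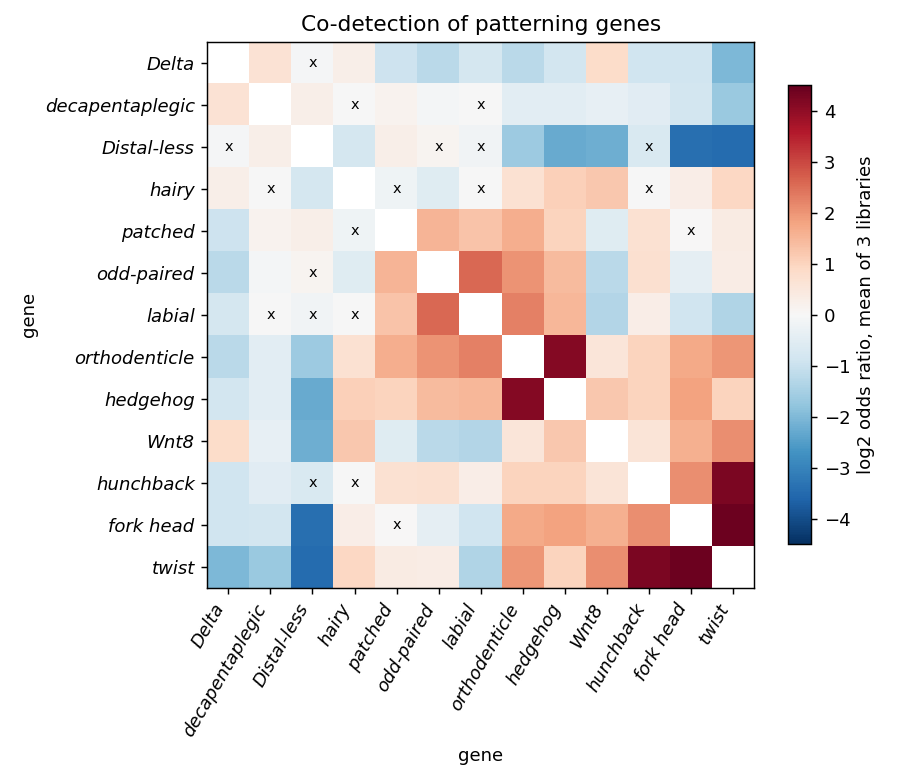
Mean over 3 libraries of the log2 odds ratio of detecting both genes of a pair in a cell, for 13 genes (red above 0, blue below 0), with x on the 10 pairs whose sign differed between libraries. The highest values are those of twist with fork head (4.42) and hunchback (4.23) and of hedgehog with orthodenticle (4.13), and the lowest those of Distal-less with twist (−3.47) and fork head (−3.40).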

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

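All tests of explanations in this part, the splits of the sums and the interaction tests were chosen after the result was seen. Differences between nuclei and cells in the effect of a reference gene were tested as an interaction in edgeR, with adjusted p under 0.05 over all genes. This called 95 genes for hedgehog, 798 for fork head, 0 for decapentaplegic and 392 for Delta. The nuclei form 1 library, so each gene's own spread came from the 2 cell libraries with 1 residual degree of freedom. EdgeR pooled it with the spread of other genes. The calls compare these libraries, and a gene could be called although its ratio in nuclei 2 lay between those of the 2 cell libraries. All differences below are log2 values of nuclei minus cells.

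In hedgehog-positive against -negative cells, 4 of the genes that were lower with hedgehog were less so in nuclei. The difference was 0.78 for Delta, 0.74 for Distal-less, 0.71 for short gastrulation and 0.45 for cubitus interruptus. The positive classes need not be alike in cells and nuclei. Hedgehog stood at 73.2 CPM in cells 2 and 760 CPM in nuclei 2. In the cluster with its lowest share, 0.840% of the cells of cells 2 and 8.25% of the nuclei had a UMI. How far this moved the differences was not tested. In fork-head-positive cells the difference was −0.63 for hedgehog, −0.56 for orthodenticle, −0.86 for hunchback, −0.84 for Distal-less, −0.60 for GATA-C, −0.83 for patched, −1.11 for short gastrulation and −0.62 for Wnt5. The 2 cell libraries also differed from each other: the log2 ratio in nuclei 2 lay between theirs for Distal-less (−3.56 and −2.40 in cells 1 and cells 2, −3.29 in nuclei 2) and GATA-C (−0.09, 0.67 and 0.16). For Wnt5 (−1.15, −0.76 and −1.37) and hedgehog (2.09, 1.50 and 1.22) the cell libraries lay further from each other than nuclei 2 from the nearer one. For patched the sign itself differed, with 0.27 in both cell libraries and −0.44 in nuclei 2. In Delta-positive cells the difference was −0.60 for labial, −0.37 for Wnt8, −0.40 for short gastrulation and −0.49 for Wnt5. Here too the ratio of Wnt8 in nuclei 2 (0.25) lay between those of cells 1 (0.12) and cells 2 (0.66), and that of short gastrulation was 0.11 in cells 1, −0.45 in cells 2 and −0.64 in nuclei 2.

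In the summed counts, cells and nuclei differed in sign for Delta in fork-head-positive cells (a difference of 1.19) and for fork head in Delta-positive cells (0.98), while detection of both in 1 cell, within deciles of depth, had 1 sign throughout (−1.32 in cells 1, −1.05 in cells 2 and −0.28 in nuclei 2). Whether 2 nuclei lay under 1 barcode could not be decided by depth. The 169 nuclei with both genes had a median of 6784 UMIs, 1.14 times that of the 450 nuclei with fork head alone (5971). The deposited filter kept no nucleus above 10669 UMIs, which limits how far this ratio could rise. Of the 169 nuclei, 74 (43.8%) lay in cluster 8, the cluster with the highest fork head at the resolution used, where Delta stood at 499 CPM. In cells 1 and cells 2 the highest fork head lay in the cluster highest in twist (171 and 136 CPM). In nuclei 2 it lay in cluster 8 (442 CPM), which was not the cluster highest in twist. Fork-head-positive cells and nuclei may therefore hold different parts of the disc, which was not tested. A biological difference between nuclear and whole-cell RNA stays open, as untested. Depth cannot be told apart: in nuclei thinned to 2500 UMIs the ratio was 0.10 (SD over 20 draws 0.16), but in cells thinned alike the lower Delta was not seen beyond the spread of the draws either (0.44, SD 0.45, in cells 1 and −0.32, SD 0.38, in cells 2). Without thinning, the signs still differed under stricter detection. Here the comparison was with all cells or nuclei holding fewer UMIs of fork head, not only those with 0, and without matching of depth. With at least 2 UMIs of fork head the ratio was 0.51 in nuclei 2, −0.88 in cells 1 and −1.10 in cells 2. With at least 4 UMIs it was 1.26 (117 nuclei), −0.27 (32 cells) and −0.88 (96 cells).

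Relative to the typical gene, 10 of 18 positional genes had lower and 8 higher fitted values in cells, and the list did not pass camera (adjusted p = 0.500, and adjusted p = 0.735 with an estimated correlation), so a shift of the group was not shown. Of the 10 with lower values, 7 had at least 30 positive cells in every library. A larger share of nuclei from the parts of the disc that use them is argued against as the whole cause for 5, provided that matched clusters hold like parts of the disc: between the cluster of cells 2 with the highest level and its best match in nuclei 2, the log2 ratio of nuclei over cells was 3.38 for hedgehog, 4.06 for labial, 2.92 for hunchback, 3.75 for odd-paired and 4.08 for decapentaplegic, above the shift of all genes (1.48), and against cells 1 all 5 were at least 3.08, above 1.14. Decapentaplegic had a UMI in 74.3% of nuclei 2, so it did not mark 1 part of the disc. Its match in nuclei 2 was cluster 7 against cells 2 but cluster 8 against cells 1, so different clusters were compared. A larger share of nuclei stays open for Wnt8 (0.99, and 1.31 against cells 1). It also stays open for Distal-less, whose 1.92 and 2.35 exceeded the shifts by 0.44 and 1.21 (SD 0.54). Nuclear RNA holding more newly made transcript of these genes remains an untested biological hypothesis, since counts of introns were not analysed here.

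Twist went the other way, higher in cells. Fewer nuclei caught from the twist part of the disc is argued against as the whole cause by the level within the twist cluster. There the log2 ratio of twist in nuclei 2 over cells 2 was −1.30, and over cells 1 it was −0.93. A smaller share may add to it: the cluster held 6.99% of nuclei 2 against 9.06% of cells 2 and 8.91% of cells 1. At resolutions 0.5 and 1.5, however, it held more of nuclei 2 (6.80% and 7.12%) than of cells 2 (5.47% and 5.63%). Free twist RNA in the cell preparations as the main source is argued against as well, at the resolution used. There 7.74% of the twist molecules of cells 2 lay outside that cluster (6.01% in cells 1 and 9% in nuclei 2). Twist is among the genes leading the cluster, so a low share outside it is partly built in. At resolutions 0.5 and 1.5 the cluster held 198 and 204 cells of cells 2, against 328, and the share outside was not counted. A more stable, mostly cytoplasmic twist transcript may be the reason, which is a hypothesis with no test of its own.

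The 10 splits of the 6 sums are too few for a share under 0.05, and only 4 of them, the real one included, put the 2 sums of each library on different sides. For hedgehog 1 split, the real one, called as many genes (439, highest other 0), and likewise 1 for fork head (2196, highest other 0) and 1 for Delta (381, highest other 8). For decapentaplegic 2 splits called as many as the real 114: exchanging the positive and negative sums of cells 1 gave 147. Each highest other value was also the highest among the splits that part every library.

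Molecules were also counted outside the columns and barcodes used. Columns named as tRNA genes held 7.59, 2.00 and 37.9 CPM in cells 1, cells 2 and nuclei 2. The barcodes removed by the deposited filter held hedgehog at 70.9, 51.3 and 413 CPM, against 62.2, 73.2 and 760 CPM in the barcodes kept.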

How the results depend on the processing

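The alternatives were chosen before the data were examined, except 2 that were chosen after seeing the data: the genes kept in the third table of each library, and clustering on the first filtered tables. Of the values that answer a comparison, 89 kept their direction and side of the threshold, or stayed within their spread or 1.5 times their count, and 26 did not. Between cells and nuclei edgeR called 0 genes with TMM, with RLE, over every barcode, in thinned libraries and over the genes kept in the third table of each library, with 3211, 3093, 3253, 3171 and 2870 at an unadjusted p under 0.05. DESeq2 called 1767, library size alone 3024 and no filter 2032, and the cause was not tested. Genes over 2-fold numbered 7221 to 7297 with 1 cell library left out, against 8090. Between the 2 cell libraries themselves, 3700 of the 12749 tested genes differed over 2-fold. The first filtered tables give the sums used throughout, so that setting moves nothing. Under library size alone the fitted folds of orthodenticle (−1.32), Delta (−1.25), fork head (−0.88), patched (−0.86), MEF-2 (−1.56), Wnt7-2 (−1.09) and wnt16-like (−0.10) turned negative, as the median of all genes moved from 0.08 to −1.53. MEF-2, at 0.05, was also at −0.033 in DESeq2 and with RLE, −0.30 in thinned libraries and −0.12 over the genes of the third tables, and the cause was not tested.

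With a reference gene, the count without a library term was 0 for hedgehog, fork head, decapentaplegic and Delta, since differences between libraries then enter the spread (36, 549, 3 and 21 at an unadjusted p under 0.05). DESeq2 called 229 for hedgehog, 3474 for fork head, 23 for decapentaplegic and 173 for Delta. RLE factors gave 4116 for fork head. For decapentaplegic thinned cells gave 279 and no filter 356. With 1 library left out the counts ran from 326 to 522 for hedgehog, 1265 to 2421 for fork head, 5 to 273 for decapentaplegic and 231 to 426 for Delta. After thinning twist with hedgehog was at −0.057 and Delta with fork head at 0.064. The cause was not tested in these cases. Of the values of named genes, 528 kept direction and side of the threshold and 102 lost their call, 53 of them without a library term.

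The mean share of the cluster highest in hedgehog was 13.8% at resolution 0.5, 7.92% at 1.5 and 11.8% on the first filtered tables, against 12.6%, and that of the cluster highest in twist was 7.06% and 7.02% at these resolutions, against 8.32%. The cause was not tested. The counts of marker lists lay near their ceiling and so tell little, and with 50 genes the median rho of the lists of nuclei 2 in cells 1 went from 0.128 to 0.0775. With at least 10 CPM, r was 0.429 for cells 1 and nuclei 2 and 0.510 for cells 2 and nuclei 2, over fewer genes of narrower range. Pairs of genes with 1 sign in every library numbered 54 to 73 across alternatives. No paired analysis was possible because the groups share only 1 replicate number. The median nucleus held 5404.5 UMIs, which limits the detection of genes with few molecules.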

Other observations

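The genes of this part lie outside the fixed lists and were chosen after their values were seen, as named in the reference gene table. The homeobox gene hox3 (LOC107440707) was at 3.50, 7.48 and 59.1 CPM in cells 1, cells 2 and nuclei 2. Its log2 odds ratios of detection were 1.50, 1.41 and 1.17 with Delta in the 3 libraries, and −1.24, −2.09 and −1.27 with hedgehog. Deformed (LOC107450665), a Hox gene, was at 5.84, 4.70 and 14.5 CPM, with log2 odds ratios of −1.85, −2.12 and −0.88 with hedgehog and −1.35, −2.21 and −3.00 with fork head. The T-box gene h15-1 (LOC107436847) was at 3.97, 23.3 and 568 CPM. In each library its highest cluster was the one highest in odd-paired. In cells 2 and nuclei 2 it led that cluster and so helped to define it, which makes this no result of its own. The log2 odds ratios of h15-1 with Delta were −0.39, −1.47 and −1.29.

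The gene filter behind the third deposited table removed 48.7% of the molecules of cells 1 through 445 genes, and 3.29% and 2.06% of cells 2 and nuclei 2 through 85 genes. Only 13 of the genes left out were the same in cells 1 and cells 2, while all 85 were the same in cells 2 and nuclei 2. Cells 1 shared 14575 gene columns with cells 2, and cells 2 shared 17798 with nuclei 2. No explanation for this was tested.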
